A study of Mus musculus with 12 samples.

How the data were processed

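RNA from whole forestomach of adult wild-type C57BL/6J mice was measured on 12 two-colour Agilent mouse expression arrays in 3 groups of 4, per the labels. The control mice drank a supersaccharin solution with 0% alcohol, the second group drank 20% alcohol in the same solution for 4 weeks, and the third drank 15% alcohol for 40 weeks, where the labels do not mention saccharin. Total RNA was extracted with a kit for fibrous tissue and labelled by linear amplification, per the labels' protocols. Cy5 carried the forestomach RNA and Cy3 carried Agilent's Universal Mouse Reference RNA on every array, per the labels, so no dye swap balanced the channels. Each group was read from the sample titles, which also number the replicates. Nothing in the labels says that replicates were separate animals, so the p-values measure the spread between these samples, which may in part be technical.

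Scanner output of Agilent Feature Extraction was used for the 8 arrays of the control and 4-week groups. It gives mean spot and median local background signals as intensity on a linear scale, per the file headers. It also gives processed signals, an intensity after the scanner software subtracted background and normalised the dyes, with log10 ratios of these processed signals, per the file headers. Flags for spots well above background, saturated or outlying, other values of 0 or 1, were taken as deposited. The headers name software version 10.7.3.1, while version 9.1 stands in the submitters' processing notes, and the difference could not be resolved. Genomic positions are those of the files, on mouse build mm9 (NCBI37), and give the probe. For the 40-week arrays the deposited value table was the only source used here, and their scanner files were not analysed here. The table holds log2 ratios of Cy5 over Cy3 as deposited by the authors. Its scale was not given in the sources used here and was found by setting its columns against the scanner files of the same 8 arrays. The log2 ratio after local background subtraction, minus a smooth curve over intensity, matched the table within a tolerance of 0.05 for 99.997% to 100% of the probes with both channels above local background, which were 96.1% to 98.5% of probes per array. Every other probe of those arrays held exactly 0. How the 40-week columns were made could not be checked in this way. Column medians ran from 0.000 to 0.067. The standard deviation over probes was 1.48 to 1.73 in the control and 4-week columns and 1.02 to 1.08 in the 40-week columns, and exact zeros numbered 633 to 1629 against 67 to 141.

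Each array held 45018 spots, of which 1639 were controls. Of 41174 probes other than controls, 26918 were named through an accession in the reference gene table, 5082 through their symbol and 817 through a synonym, 808 kept the name in the files, and 7549 had no name. Signals were background-corrected with normexp (offset 50) and normalised within each array by loess, with controls and outlier spots (111 to 187 per array) left out. No Cy5 spot was saturated. Between 64.8% and 78.8% of spots per array were well above background in Cy5 and between 72.9% and 84.9% in Cy3, and the number of arrays limits the precision. A probe was kept if Cy5 was well above background on at least 3 of the 4 arrays of at least 1 group with scanner files, which left 30447 probes. The brightest probe stood for each of 17153 symbols, 6860 of which had more than 1 kept probe, and unnamed probes stood for themselves, which made 20736 genes. The same probes were used for the 40-week arrays. Since those arrays had no part in the filter, a transcript present at 40 weeks alone was not seen.

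Controls and 4-week arrays were compared with limma (lmFit and eBayes) on the scanner log2 ratios of the 8 arrays. For 40 weeks against control, and for 40 weeks against 4 weeks, limma was fitted to the deposited value table with all 12 samples in 3 groups, without further normalisation. The 4-week comparison was repeated in that second fit. Every adjusted p is a Benjamini-Hochberg value from limma, or from limma's camera for gene lists, and a gene was called at an adjusted p under 0.05. The overlap of the alcohol responses was set beside 100 simulated data sets of unchanged groups against shared controls, and beside splits of the controls. The channels were also fitted each by itself, without loess, after background correction and quantile normalisation of that channel over arrays. Where a probe was not well above background on any array of a group, only a bound is given, which is open to dye bias. The bound sets control against 4-week arrays and says nothing about 40 weeks.

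Gene lists were fixed before the data were examined, as were the groups, designs, named-gene rule and most alternative settings. The lists covered alcohol and aldehyde metabolism, NRF2 targets and glutathione, xenobiotic cytochrome P450s, retinoid metabolism, cornified envelope and keratinocyte differentiation, basal keratinocytes, stress keratins and alarmins, cell cycle, DNA repair and the Fanconi pathway, p53 targets, the unfolded protein response, heat shock proteins, immediate early genes, cytokines and chemokines, interferon response, T and NK cells, B and plasma cells, macrophages and dendritic cells, granulocytes and mast cells, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and PPAR targets, oxidative phosphorylation, glycolysis and hypoxia, eicosanoid synthesis, circadian clock, glucocorticoid response, extracellular matrix, fibroblasts, smooth muscle, skeletal muscle, glandular stomach, pancreas acinar cells, adipocytes, red blood cells, enteric neurons and glia, endothelium, ribosomal proteins and sex-chromosome genes. All 39 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, which asks only whether the members of a list move one way on balance. Genes were named by rule: the 10 called genes with the largest rise and the 10 with the largest fall that carry a proper symbol (5 each between the alcohol groups), called members of each list with the smallest adjusted p, and Adh1, Adh7, Aldh2, Aldh1a1, Aldh3a1 and Cyp2e1 whatever their result. The rule allowed up to 4 members per list. After the data were seen, this part was narrowed at 40 weeks to 2 members of each list that camera called, and dropped between the alcohol groups, because nearly every list then had many called members. Not every gene the rule selects is printed, and withheld items among them are not reported here.

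On simulated data with 100 genes changed by each size, the 4-week fit recovered 76% of changes of 1 and 94% of changes of 2 on the log2 scale with 8 false calls over 20736 genes. The 40-week fit recovered 61% and 93% with 6 false calls, and the fit between the alcohol groups 67% and 94% with 10 false calls. The simulated genes varied independently of each other, with a spread taken from the fit itself and no shifts between slides or whole arrays. These counts therefore check the fit and do not give the rate of false calls in the real data. The alternatives varied the background correction, normalisation within and between arrays, filter on dim probes, probe per gene, reference channel, variance model, array weights, replicate number as a block and omission of each replicate. Alternatives chosen after the data were seen left out arrays with transcripts of other organs or with another sex-chromosome pattern, scaled the table's columns to 1 spread, took its zeros as missing, and applied some of the other settings to the lists. Software was R 4.3.3 with limma 3.58.1 and the data.table package (version 1.17.8), and python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. All control arrays lay on 1 slide scanned on 1 day, and all 4-week arrays on another slide scanned on another day, so batch and group cannot be told apart. Slide and scan day of the 40-week arrays were not analysed here.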

Results

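Gene expression in mouse forestomach, the part of the rodent stomach lined by a keratinised squamous epithelium, was measured in 4 control samples, 4 samples after 4 weeks of 20% alcohol and 4 samples after 40 weeks of 15% alcohol. Each array gives, per gene, the log2 ratio of forestomach RNA in Cy5 to a commercial reference RNA pool in Cy3. Median Cy5 signal above background was 112 to 151 on the control arrays and 42.4 to 112 on the 4-week arrays. Pearson correlations of log2 ratios across genes, which are not independent replicates, were 0.889 to 0.963 among controls, 0.889 to 0.970 among 4-week arrays and 0.826 to 0.967 between these groups. In the deposited values they were 0.938 to 0.974 among 40-week arrays and 0.773 to 0.907 between these and controls. Both comparisons with controls ask whether drinking alcohol changes expression in the forestomach, and the comparison of the alcohol groups asks whether the responses differ. The 40-week mice had no controls of their own and differed from these controls in cohort and probably age as well. Some 40-week samples also differed in sex-chromosome genes. That comparison therefore cannot set alcohol apart from these differences.

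Transcripts of other organs stood out on 3 arrays. Pancreatic digestive enzyme genes were over 1 on the log2 scale above the mean of the other 3 controls for 95.5% of 22 measured pancreas genes in control replicate 3. Glandular stomach genes were that far above the other 3 arrays of their group for 81.8% of 22 genes in control replicate 4 and for 86.4% in 4-week replicate 2. In these latter arrays 55.6% and 77.8% of interferon response genes were raised in the same way, and 54.5% of pancreas genes in 4-week replicate 2. Sex-chromosome genes separated 40-week replicates 3 and 4 from all other samples. Xist, the RNA that coats the inactive X chromosome, had log2 ratios of 1.96 and 1.55 in them and of -9.70 to -5.40 elsewhere. The Y-linked genes Eif2s3y and Ddx3y had -5.67 and -6.28, and -4.26 and -4.02, against 2.61 to 3.17 and 0.49 to 1.49 elsewhere. This is the pattern of female samples in 40-week replicates 3 and 4 and of male samples elsewhere, though the labels give no sex.

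**Figure D1:**
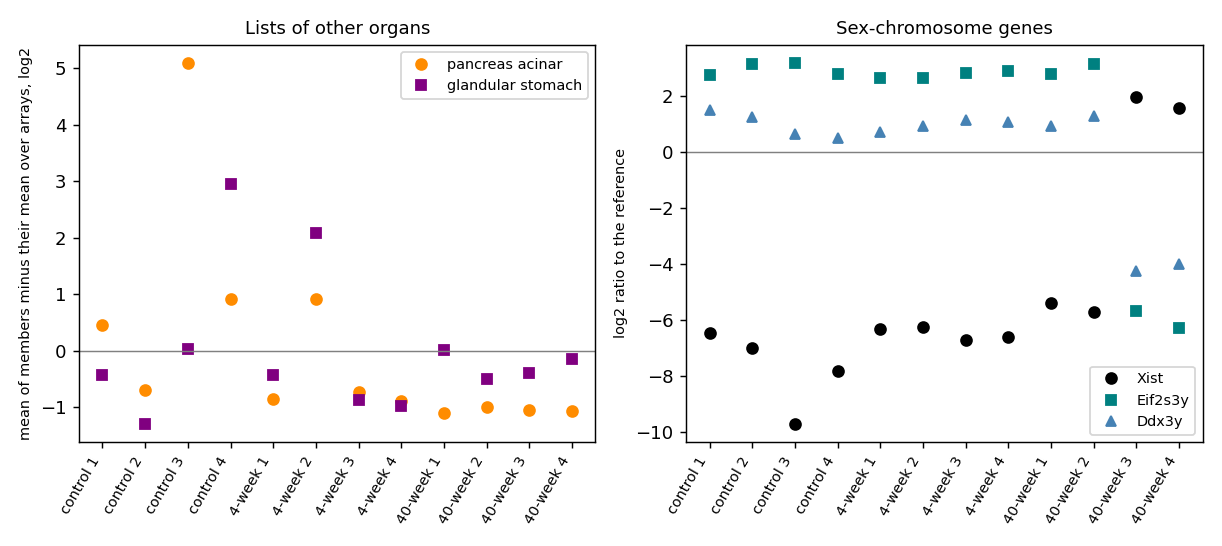
Left, mean deviation of the pancreas acinar and glandular stomach lists per array from each gene's mean over the 12 arrays (log2); right, log2 ratio to the reference of Xist, Eif2s3y and Ddx3y per array, each point 1 array. The pancreas list stands highest in control replicate 3 and the glandular list in control replicate 4 and 4-week replicate 2, while 40-week replicates 3 and 4 alone have Xist above 0 with Eif2s3y and Ddx3y below 0.

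After 4 weeks of 20% alcohol, 58 genes rose in the ratio to the reference. Ubl7, which encodes a ubiquitin-like protein, rose by 1.17 ± 0.17 (log2 ± SE, n = 4 against 4; limma adjusted p = 0.0347), Ciart, a repressor of the circadian clock, by 1.14 ± 0.17 (adjusted p = 0.0347), and Txnip, an inhibitor of thioredoxin and of glucose uptake, by 1.07 ± 0.19 (adjusted p = 0.0426). Genes of the cornified layer of the epithelium and of smooth muscle fell in the ratio, among them the muscle protein calponin 1 (Cnn1) by 2.10 ± 0.31 and keratin 10 (Krt10), a keratin of differentiating epidermis, by 1.79 ± 0.26 (adjusted p = 0.0347 each). For most of these genes the forestomach channel moved little while the reference channel was brighter on the 4-week slide, by 1.98 for Cnn1 and 1.80 for Krt10, so the fall of the ratio is not shown to be a loss of transcript from the tissue.

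With limma, 229 of 20736 genes were called, 58 higher and 171 lower, of which 206 had a symbol and 110 changed more than 2-fold, and 3731 genes had an unadjusted p under 0.05. In all 229 the 4-week and control arrays did not overlap. Over all genes 11.8% showed no overlap, where chance gives 2.86%. Other kept probes of called genes had the same sign in 81 of 101 cases (80.2%). No gene was called without control replicate 2, 3 or 4 or 4-week replicate 1, with 2971, 3896, 3883 and 3212 genes at an unadjusted p under 0.05, and 1, 1, 16 and 52 genes were called without control replicate 1 and 4-week replicates 4, 2 and 3. Median centring in place of loess, which moved the median of all genes to -0.11, and scaling of every array to 1 spread each also gave 0 calls (2819 and 3165 genes at an unadjusted p under 0.05), as did leaving out the 3 arrays with transcripts of other organs (4573). Without background correction 558 genes were called, with a smaller normexp offset 136, with the scanner software's processed signals 669 (36.2% higher against 25.3%), with array weights 475, from the deposited values of these 8 arrays 145, and in Cy5 alone 75, of which 80% were higher and 19 were among the 229.

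The 58 genes that rose had a median change of 0.73 in the ratio, 0.70 in Cy5 and -0.05 in Cy3, and all 58 were higher in Cy5, 56 of them at an unadjusted p under 0.05 and 8 with an adjusted call. They were chosen by a ratio that holds the same Cy5 values, so a higher Cy5 is no separate support. Slide and group coincide in Cy5 as well. Besides those above, the largest rises were of Hebp1 (1.12 ± 0.19), a heme-binding protein, Spint2 (1.12 ± 0.20), an inhibitor of serine proteases, Arsk (1.07 ± 0.15), a lysosomal sulfatase, and Mocs1 (0.98 ± 0.18), an enzyme of molybdenum cofactor synthesis. Arrdc2 (0.92 ± 0.17) encodes an arrestin-domain protein, as Txnip does, Trub2 (0.92 ± 0.17) a pseudouridine synthase, and Galc (0.91 ± 0.12) a lysosomal enzyme that removes galactose from galactolipids. The other kept probe of Arsk had the opposite sign, as had 1 of the 2 others of Galc. In the Cy5 channel alone the changes were 1.18 for Ubl7, 1.86 for Ciart, 1.48 for Spint2, 1.09 for Hebp1 and 0.97 for Txnip, and limma called the first 3 of these (adjusted p = 0.0452, 0.0276 and 0.0355). Cy3 was also higher for Ciart (0.82) and Spint2 (0.79). The probe of Ubl7 lies on chromosome 9 at 57777619 to 57777678, that of Ciart on chromosome 3 at 95682433 to 95682492 and that of Txnip on chromosome 3 at 96365147 to 96365206.

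The 171 genes that fell in the ratio had a median change of -1.12, with -0.45 in Cy5 and 0.59 in Cy3. In Cy5 128 of them were lower, 80 at an unadjusted p under 0.05 and 11 with an adjusted call. Their median control log2 ratio was 4.87, against 0.10 over all genes, so their Cy5 signal lay far above the reference. The reference RNA should be alike on both slides, yet limma called 1795 genes in Cy3 alone, 1240 of them higher on the 4-week slide. Among genes with a control Cy3 log2 signal of 7 to 9, the median shift of raw Cy3 minus background was -0.35 for 667 genes with a control Cy5 signal under 6. It was 0.54 for 131 genes with one of 12 to 14. Unlike the other Cy3 changes, these shifts were not normalised over arrays, and raw Cy3 was dimmer on the 4-week slide in general. The -0.35 is therefore not shown to be a fall particular to genes dim in Cy5. After normalisation the median Cy3 change of all genes was -0.03.

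Cornified envelope and keratinocyte differentiation genes, which build the tough outer layer of squamous epithelium, had a median change of -1.23 in the ratio, and 43 of 48 measured members were lower. Of these, 18 fell and none rose (37 fell adjusted over the list alone), with a camera adjusted p of 2.55e-23 and an adjusted p = 0.355 with an estimated correlation. Examples are Crct1 (-1.92 ± 0.35), Lce1m (-1.75 ± 0.22) and Spink5 (-1.72 ± 0.24), a protease inhibitor, together with the keratin Krt4 (-1.50 ± 0.21). In Cy5 alone the list had a median of 0.15 and was called in the opposite direction (camera adjusted p = 0.0237), and in Cy3 its median was 1.36. Krt4 had 0.73 in Cy5 and 2.01 in Cy3, Crct1 had -0.03 and 1.89, and Lce1m had -0.55 and 1.16. The median raw Cy3 signal of the list was 1159 to 1481 on the control arrays and 2537 to 3710 on the 4-week arrays, although the median Cy3 signal of all probes was lower on the latter, 191 to 221 against 232 to 269.

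**Figure D2:**
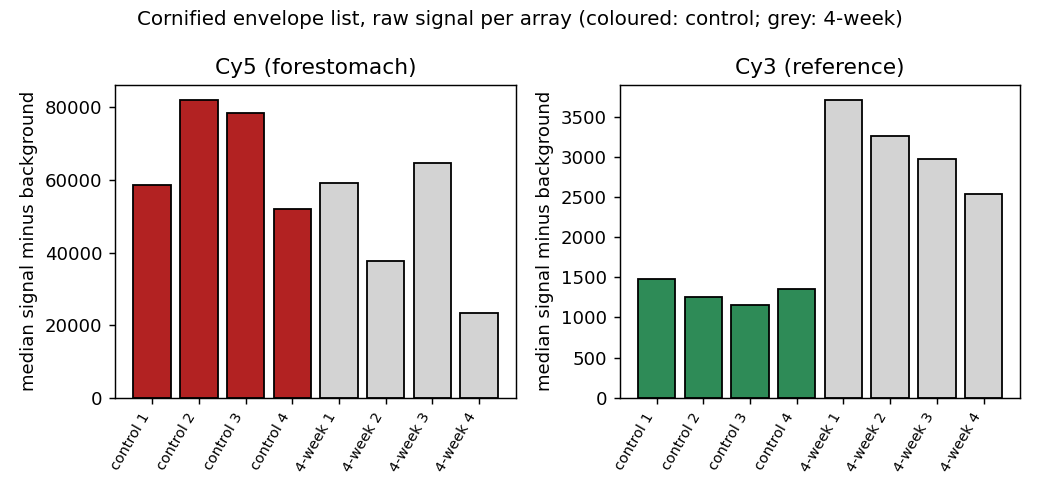
Median signal minus background of the cornified envelope list on each of the 8 scanned arrays (linear scale; 1 bar per array; coloured bars control, grey bars 4-week), left in Cy5 and right in Cy3. In Cy3, which holds the same kind of reference RNA on every array, all 4-week arrays (2537 to 3710) stand above all control arrays (1159 to 1481).

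Smooth muscle genes fell in the ratio with a median of -0.80, all 23 were lower, and 5 passed the test (16 adjusted over the list alone; camera adjusted p = 1.99e-13; adjusted p = 0.315 with an estimated correlation). Desmin (Des), the muscle intermediate filament, fell by 1.24 ± 0.19, with -0.68 in Cy5 and 0.49 in Cy3, and smooth muscle myosin heavy chain (Myh11) fell by 1.59 ± 0.28, with -0.27 and 1.21. The list was lower in Cy5 as well, with a median of -0.19 (camera adjusted p = 0.00586), and its ratio had a median of -0.35 after scaling of every array to 1 spread. Stress keratins and alarmins, proteins made by irritated epithelium, had a median of -0.70 with 26 of 30 members lower. Of these 5 fell (12 adjusted over the list alone; camera adjusted p = 4.42e-08; adjusted p = 0.355 with an estimated correlation), among them S100a9 by 1.55 ± 0.18 and Serpinb3c by 1.43 ± 0.25. In Cy5 the list had a median of -0.30 and was not called (camera adjusted p = 0.0894), and scaling of every array to 1 spread also ended its call.

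Of the 171 genes that fell in the ratio, 128 were lower in Cy5 and 11 were called there. Among the named genes a few falls were carried mainly by the forestomach channel, though none of those below was called in it alone. Serpinb3c, a serine protease inhibitor, had -1.42 in Cy5 and -0.05 in Cy3. The muscle enolase Eno3 fell by 1.13 ± 0.20 (limma adjusted p = 0.0426), with -1.42 and -0.15, and the alcohol dehydrogenase Adh6a fell by 0.90 ± 0.14 (adjusted p = 0.0349), with -0.66 and 0.15. By contrast, Aldh3b2, an aldehyde dehydrogenase, fell by 1.54 ± 0.22 in the ratio but had 0.50 in Cy5 and 1.82 in Cy3, and Gpx2, a glutathione peroxidase, fell by 1.88 ± 0.25 with 0.15 and 1.88. Alcohol and aldehyde metabolism genes as a list were not called (median -0.20, 13 of 21 lower, 2 fell; camera adjusted p = 0.401). Of the enzymes of ethanol oxidation, Adh1 had -0.49 ± 0.17 (limma adjusted p = 0.187), Adh7 -0.06 ± 0.24 (0.927), Aldh2 0.45 ± 0.24 (0.376), Aldh1a1 0.26 ± 0.20 (0.538), Aldh3a1 0.08 ± 0.22 (0.889) and Cyp2e1 -1.01 ± 1.33 (0.737), so none passed the test. Cyp2e1 was well above background on 3 of the 4 4-week arrays, and the other kept probe of Aldh2 had the opposite sign. The log2 ratio of Cyp2e1 was low in control replicate 1 (0.82 against 5.32 to 5.98) and in 4-week replicate 3 (0.34 against 4.27 to 4.65). Adipocyte genes stood low in the same arrays. Aldh3a1 had 1.43 in Cy5 and 1.35 in Cy3, and Adh1 and Adh7 had 0.39 and 0.68 in Cy5.

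**Figure D3:**
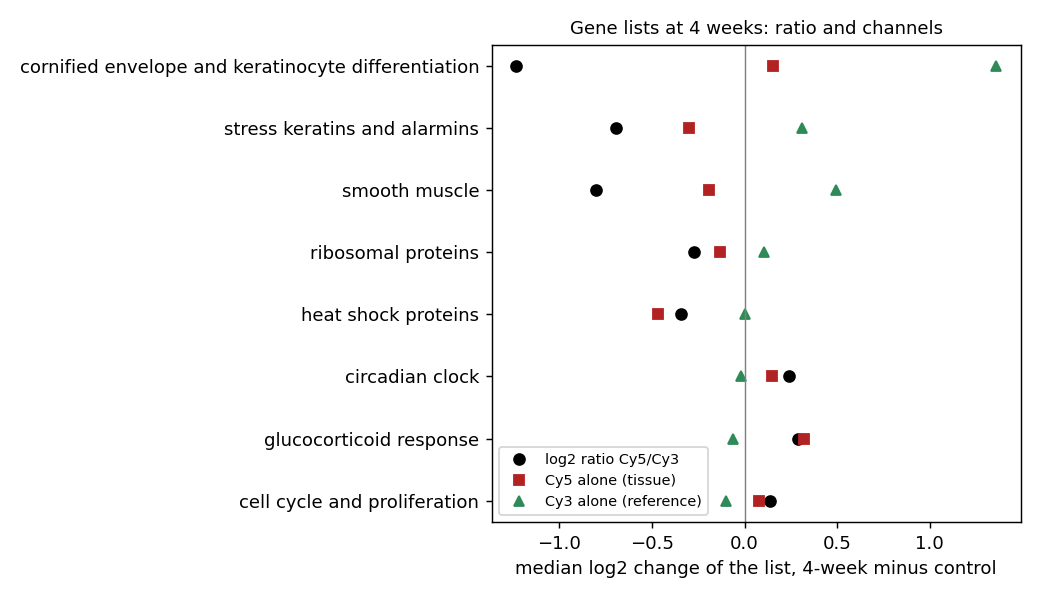
Median log2 change of 8 gene lists, 4-week minus control, in the ratio (circles), in Cy5 alone (squares) and in Cy3 alone (triangles). For cornified envelope genes the ratio lies at -1.23 with Cy5 at 0.15 and Cy3 at 1.36, while for glucocorticoid response genes ratio (0.29) and Cy5 (0.32) lie together and Cy3 (-0.06) near 0.

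Glucocorticoid response genes, induced by stress hormones, had a median of 0.29 with 12 of 15 members higher. Of these Cdkn1a, the cell cycle inhibitor p21, rose by 0.63 ± 0.12 (limma adjusted p = 0.0469; 3 rose adjusted over the list alone; camera adjusted p = 0.00206; adjusted p = 0.315 with an estimated correlation), and the list was called in Cy5 too (median 0.32; camera adjusted p = 0.0197). Circadian clock genes had a median of 0.24 with 13 of 20 higher, where only Ciart rose (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0220; adjusted p = 0.672 with an estimated correlation). That call ended in Cy5 alone and without control replicate 3 or 4 or 4-week replicate 1 (adjusted p = 0.0534, 0.0753 and 0.0823). Cell cycle genes had a median of 0.14 with 32 of 43 higher and no member called (camera adjusted p = 0.0212; adjusted p = 0.839 with an estimated correlation). Their median turned to -0.12 when every array was scaled to 1 spread, and the call ended in Cy5 alone and without control replicate 2 or 4 or 4-week replicate 4 (adjusted p = 0.313, 0.0842 and 0.249). Heat shock genes had a median of -0.34 with 17 of 21 lower and no member called (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.00626; adjusted p = 0.758 with an estimated correlation), and were lower in Cy5 as well (-0.47; camera adjusted p = 0.0197).

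Ribosomal protein genes had a median of -0.27 with 34 of 39 lower and none called (10 fell adjusted over the list alone; camera adjusted p = 6.18e-07; adjusted p = 0.355 with an estimated correlation). Red blood cell genes had -0.52 with all 10 lower, and Car2 fell, with 0.09 in Cy5 and 1.06 in Cy3 (4 adjusted over the list alone; camera adjusted p = 1.44e-04; adjusted p = 0.355 with an estimated correlation). Macrophage and dendritic cell genes had -0.33 with 23 of 29 lower, and the complement gene C1qc fell, with 0.11 in Cy5 and 1.12 in Cy3 (5 adjusted over the list alone; camera adjusted p = 9.75e-04; adjusted p = 0.812 with an estimated correlation). Adipocyte genes had -0.78 with 18 of 19 lower, and 2 fell, Fabp4, with -0.20 in Cy5 and 1.14 in Cy3, and the glucose transporter Slc2a4, with -0.42 and 0.61 (3 adjusted over the list alone; camera adjusted p = 0.00103; adjusted p = 0.719 with an estimated correlation). The macrophage and adipocyte calls ended in Cy5 alone and after scaling to 1 spread, and the macrophage, red cell, circadian and cell cycle calls ended without the 3 arrays with transcripts of other organs (medians 0.02, -0.20, 0.28 and 0.06). The adipocyte list differed widely between single arrays. Its median raw Cy5 signal was 721 in control replicate 1 against 7459 to 9402 in the other controls. In 4-week replicate 3 it was 98.6 against 3006 to 7618 in the rest of that group. Pancreas genes had -1.60 with all 22 lower and none called, alone or over all genes (camera adjusted p = 9.96e-04; adjusted p = 0.839 with an estimated correlation), and their median was -0.32 without control replicate 3, with the call kept. With an estimated correlation camera called 0 of the 39 lists (4 at an unadjusted p under 0.05), and fry called 6. In Cy5 alone 8 lists were called, 6 of them among the 12 and in the same direction.

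Fatty acid oxidation and PPAR target genes had a median of 0.13 (camera adjusted p = 0.0573), Cpt1b, which carries fatty acids into mitochondria, rose by 0.73 ± 0.12 (limma adjusted p = 0.0401), and the list was called in Cy5 alone (0.31; camera adjusted p = 0.00586), after scaling to 1 spread (0.39), without control replicate 2 or 3 or 4-week replicate 1 or 2 (0.16, 0.21, 0.17 and 0.15) and without the 3 arrays with transcripts of other organs (0.18). Its adjusted p ran from 2.44e-04 to 0.293 over the settings. NRF2 target and glutathione genes had 0.03 (camera adjusted p = 0.478) and were called after scaling to 1 spread (0.21), with Gclm, a subunit of the enzyme that limits glutathione synthesis, up by 0.71 ± 0.13 (limma adjusted p = 0.0426) and Gpx2 lower. The interferon list had 0.20 (camera adjusted p = 0.550), which turned to -0.42 (0.00583) without 4-week replicate 2 and was called at 0.42 without 4-week replicate 3. The glandular stomach list had -0.24 (0.478), which became -1.14 (0.00673) without 4-week replicate 2. The endothelium list had -0.19 (0.0573) and was called without control replicate 1 or 3 or 4-week replicate 3 (-0.17, -0.20 and -0.20), without background correction (-0.29), with processed signals (-0.26) and with genes well above background on all 8 arrays (-0.21), while it had 0.16 with no call after scaling to 1 spread. The other lists were not called by camera either: medians were -0.05 for cytochrome P450s (0.478), 0.03 for retinoid metabolism (0.996), -0.19 for basal keratinocytes (0.366), 0.01 for DNA repair (0.380), -0.04 for p53 targets (0.967), -0.01 for the unfolded protein response (0.967), 0.13 for immediate early genes (0.254) and -0.20 for cytokines (0.354). They were -0.14 for T and NK cells (0.401), 0.00 for B cells (0.882), -0.06 for granulocytes and mast cells (0.607), -0.04 for cholesterol synthesis (0.967), -0.05 for fatty acid synthesis (0.996), 0.03 for oxidative phosphorylation (0.631), 0.07 for glycolysis (0.433) and -0.07 for eicosanoid synthesis (0.436). The remaining medians were 0.02 for extracellular matrix (0.379), -0.00 for fibroblasts (0.967), -0.03 for skeletal muscle (0.542), -0.01 for enteric neurons and glia (0.607) and 0.13 for sex-chromosome genes (0.569). Camera called immediate early genes without control replicate 2 (0.19) and extracellular matrix without control replicate 1 or 4-week replicate 2 (0.13 each). For retinoid metabolism and oxidative phosphorylation camera pointed down against a median above 0, and for p53 targets, the unfolded protein response, cholesterol synthesis, fatty acid synthesis and fibroblasts it pointed up against a median under 0.

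After 40 weeks of 15% alcohol, cornified envelope genes fell in the ratio to the reference, and Neat1 and Rev1 were among the named genes that rose in it. Krt1, a keratin of differentiating epidermis, fell by 4.41 ± 0.28 (log2 ± SE, n = 4 against 4; limma adjusted p = 1.20e-06) and Ivl, which encodes the envelope protein involucrin, by 3.42 ± 0.20 (adjusted p = 8.23e-07). Neat1, the RNA scaffold of nuclear paraspeckles, rose by 3.17 ± 0.44 (adjusted p = 1.75e-04), and Rev1, a DNA polymerase that copies past damaged bases, by 2.91 ± 0.31 (adjusted p = 2.26e-05). The 40-week ratios spanned a narrower range than those of both other groups, with a standard deviation over probes of 1.02 to 1.08 against 1.48 to 1.73. Quantile normalisation, which gives every array 1 distribution, left Krt1 at -2.26, Ivl at -1.75, Neat1 at 3.12 and Rev1 at 2.67, each still called. The separate channels of the 40-week arrays were not analysed here. A shift in the reference channel, as seen for cornified envelope genes on the 4-week slide, therefore cannot be told apart from a change in the tissue.

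With limma, 8823 of 20736 genes were called, 3918 higher and 4905 lower, and 7152 of them had a symbol. In 7767 the groups did not overlap. Over all genes 42.4% showed no overlap, where chance gives 2.86%. Fold changes correlated at -0.776 across genes with the control log2 ratio, a value that also enters the fold change, and genes are not independent replicates. After quantile normalisation 7879 genes were called, 5336 of them among the 8823, and with every column scaled to 1 spread 7939, of which 51.3% were higher against 44.4% before. Of other probes of called genes, 2822 of 4053 (69.6%) had the same sign. Without 40-week replicates 3 and 4, whose sex-chromosome genes differed, 5058 genes were called.

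**Figure D4:**
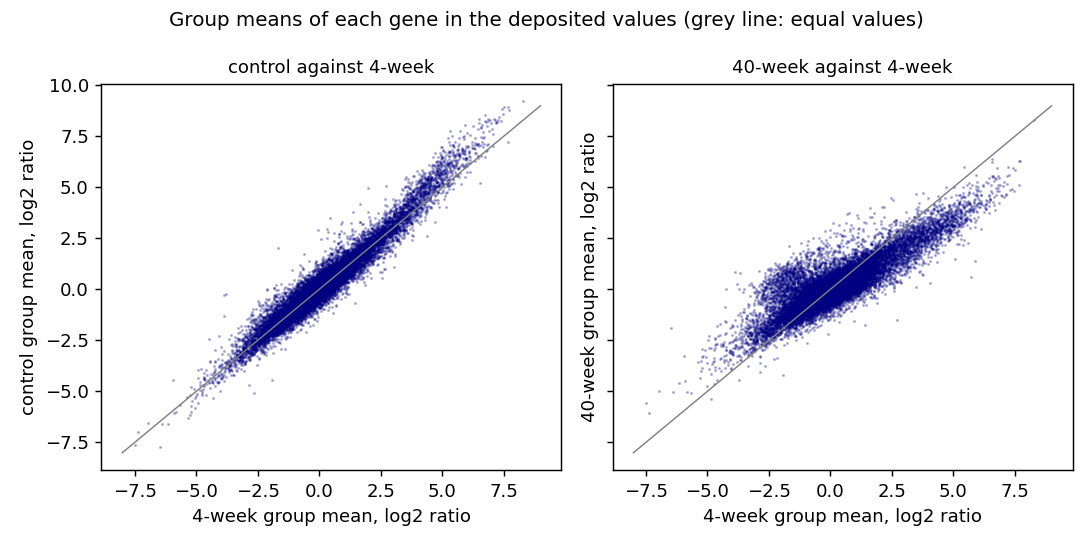
Mean log2 ratio of each gene in the control group (left) and the 40-week group (right) against its mean in the 4-week group, in the deposited values, with 1 point per gene and the grey line marking equal values. Among genes over 1 at 4 weeks the slope on the 4-week values was 1.16 for controls and 0.731 for the 40-week group, and among genes under -1 it was 0.973 and 0.691.

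Besides Neat1 and Rev1, the largest rises were of Xist (5.84 ± 1.59), the splicing factor Srrm3 (3.07 after quantile normalisation), the chemokine Cxcl10 (3.04 ± 0.82), Snhg20 (2.99 ± 0.21), a long non-coding RNA, Clec2d (2.99 ± 0.21), a ligand of natural killer cell receptors, L3mbtl2 (2.98 ± 0.30), a Polycomb protein, Tsix (2.94 ± 0.52), the antisense RNA of Xist, and Acrbp (2.93 ± 0.38). Xist rested on 40-week replicates 3 and 4 (SD 4.23 over the 40-week group). Its call ended in 4 settings, among them quantile normalisation (limma adjusted p = 0.0571), array weights and omission of control replicates 3 and 4. Over all settings its value was as low as 2.18. Cxcl10 had an SD of 2.18 and its groups overlapped. It had 1.28 and was not called without 40-week replicates 3 and 4, and array weights also ended its call. The other 6 kept their call after quantile normalisation, from 2.47 for Tsix to 3.18 for Acrbp. The probe of Neat1 lies on chromosome 19 at 5842564 to 5842623. The largest falls were of Rab38 (-5.97 ± 1.35), Sult1d1 (-4.60 ± 0.84), Crct1 (-4.42 ± 0.33), Calm4 (-4.41 ± 0.32), a calmodulin-like protein of skin, Serpinb12 (-4.31 ± 0.35) and Crisp1 (-4.23 ± 0.34). Rab38, a small GTPase, had an SD of 3.72 among the 40-week samples. After quantile normalisation these 6 lay between -4.73 for Rab38 and -2.07 for Crct1, all still called. The probe of Krt1 lies on chromosome 15 at 101676107 to 101676166, and the other kept probe of Krt1 had the opposite sign.

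Cornified envelope genes fell in the ratio with a median of -2.49. All 48 were lower, 46 fell and none rose (47 adjusted over the list alone; camera adjusted p = 3.26e-24; adjusted p = 0.208 with an estimated correlation). After quantile normalisation the median was -0.71, 28 members fell and 2 rose (camera adjusted p = 1.32e-04). Macrophage and dendritic cell genes fell with a median of -1.07, 25 of 29 lower, 17 called lower and 1 called higher, among them C1qc (-2.21 ± 0.16) and the antigen-presenting H2-Ab1 (-2.02 ± 0.17). The list had 18 lower members adjusted over the list alone, a camera adjusted p of 2.64e-05 and an adjusted p = 0.397 with an estimated correlation. After quantile normalisation its median was -0.69 (camera adjusted p = 0.00477). Eicosanoid synthesis genes, which make prostaglandins and related lipids, fell with a median of -1.06 and 16 of 24 lower. Of the members 13 fell and 2 rose (15 and 3 adjusted over the list alone; camera adjusted p = 0.00295; adjusted p = 0.208 with an estimated correlation), such as the phospholipase Pla2g4f (-2.81 ± 0.17), and the quantile-normalised median was -0.64 (camera adjusted p = 0.0203).

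Red blood cell genes fell with a median of -1.29, all 10 lower and 8 called, such as the globin Hba-a2 (-2.79 ± 0.24; 8 adjusted over the list alone; camera adjusted p = 2.72e-04; adjusted p = 0.208 with an estimated correlation; quantile-normalised median -0.75, adjusted p = 0.0203). Ribosomal protein genes fell with a median of -0.27, 32 of 39 lower and 17 called (17 adjusted over the list alone; camera adjusted p = 0.00610; adjusted p = 0.498 with an estimated correlation; quantile-normalised median -0.24, adjusted p = 0.0203). Pancreas genes were lower in all 22 members with a median of -2.36, 6 were called (4 adjusted over the list alone; camera adjusted p = 0.00285; adjusted p = 0.688 with an estimated correlation; quantile-normalised median -2.01, adjusted p = 0.00637), and their median was -1.30 without control replicate 3, with the call kept.

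The alcohol and aldehyde metabolism list had a median of -0.75 with 18 of 21 lower. Of these 13 fell (14 fell and 1 rose adjusted over the list alone; camera adjusted p = 3.27e-04; adjusted p = 0.205 with an estimated correlation). Quantile normalisation ended the call of the list (median -0.35, adjusted p = 0.675), while both alcohol dehydrogenases Adh6a (-2.92 ± 0.16) and Adh1 (-2.43 ± 0.16) kept theirs at -1.09 and -0.73 (limma adjusted p = 0.00145 and 0.00297). Adh7, the alcohol dehydrogenase of upper digestive epithelia, had -0.46 ± 0.21 (adjusted p = 0.0915) in the deposited values and 1.61 (1.35e-04) after quantile normalisation. Aldh1a1 turned in the same way, from -0.75 ± 0.19 (0.00874) to 0.88 (0.00210), so the direction of neither gene is settled. Aldh3a1 had -1.35 ± 0.19 (2.36e-04) and -0.32 (0.213), Cyp2e1 -2.52 ± 0.83 (0.0287) and -0.63 with no call, and Aldh2, again with an opposite other probe, 0.27 ± 0.23 (0.367) and 0.48 with no call. The limma call for Cyp2e1, 40 weeks against control, also ended without any 1 of 40-week replicates 1 to 4 (-2.46, -2.51, -2.55 and -2.57) or of control replicates 2, 3 and 4 (-2.32, -2.16 and -2.28). In the scanner ratios Cyp2e1 was low in control replicate 1, where adipocyte genes stood low too. Aldh1a1 lost its call without 40-week replicates 3 and 4 together (-0.66) and without control replicates 3 and 4 together (-0.48), and Adh7 gained one without control replicate 4 (-0.68).

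Further lists were called in the deposited values and lost the call after quantile normalisation. Medians were -1.78 for smooth muscle (20 of 23 fell, 21 adjusted over the list alone; camera adjusted p = 1.20e-10), -1.86 for stress keratins (21 of 30 fell and 1 rose, 23 and 2; 2.34e-09), -1.23 for endothelium (13 of 21 fell and 1 rose, 13 and 1; 6.79e-06) and -0.52 for fatty acid oxidation (15 of 30 fell, 15; 2.72e-04). They were -1.25 for granulocytes and mast cells (11 of 19 fell and 1 rose, 11 and 1; 0.00210), -0.72 for enteric neurons and glia (12 of 24 fell, 14; 0.00281), -0.82 for basal keratinocytes (10 of 19 fell, 12; 0.00285), -0.81 for cytochrome P450s (8 of 18 fell and 1 rose, 8 and 2; 0.0162) and -1.43 for adipocytes (7 of 19 fell and 2 rose, 9 and 2; 0.0169). The higher ones were DNA repair (0.45; 18 of 36 rose and 3 fell, 18 and 4; 3.96e-04), immediate early genes (0.52; 10 of 26 rose and 2 fell, 10 and 2; 0.00393) and glycolysis (0.43; 12 of 30 rose and 1 fell, 12 and 1; 0.00566). With an estimated correlation none of the 12 kept its call (adjusted p from 0.205 to 0.498). After quantile normalisation the medians of basal keratinocytes, cytochrome P450s, adipocytes, endothelium, enteric neurons, DNA repair and glycolysis changed sign.

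Cell cycle genes were called in opposite directions, with a median of 0.55 in the deposited values (38 of 43 higher; 20 rose, 21 adjusted over the list alone; camera adjusted p = 1.62e-06; adjusted p = 0.397 with an estimated correlation) and -0.48 after quantile normalisation (camera adjusted p = 0.00961). Circadian clock genes had 0.22 (14 of 20 higher, 6 rose; camera adjusted p = 0.0589) and 0.53 after quantile normalisation (15 higher, 10 rose; 0.00637), and they were called as deposited without control replicate 2 or 40-week replicate 4 (0.25 and 0.26). NRF2 targets had -0.04 (0.556) and 0.34 (0.0203). With an estimated correlation after quantile normalisation, camera's adjusted p was 0.832 for circadian clock and 0.967 for cell cycle and NRF2 targets, and at least 0.832 for every list called there. By camera 20 of the 39 lists were called, 4 higher and 16 lower. With an estimated correlation 0 were called (7 at an unadjusted p under 0.05), fry called 28, and after quantile normalisation camera called 9, of which 6 were among the 20 in the same direction. The adipocyte call ended without control replicate 4 (-1.08).

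No camera call was made for cholesterol synthesis (median -0.40; 0.0589), which was called without 40-week replicate 2 or control replicate 4 (-0.50 and -0.39), without control replicates 3 and 4 together (-0.41) and with no filter on dim probes. The other uncalled lists had medians of -0.17 for retinoid metabolism (0.516), 0.05 for p53 targets (0.335), 0.04 for the unfolded protein response (0.591), -0.20 for heat shock (0.693), 0.62 for cytokines (0.516), 0.24 for interferon response (0.345), -0.03 for T and NK cells (0.519), 0.49 for B cells (0.166) and -0.15 for fatty acid synthesis (0.447). They were -0.13 for oxidative phosphorylation (0.335), 0.10 for glucocorticoid response (0.633), 0.05 for extracellular matrix (0.447), -0.32 for fibroblasts (0.454), -0.49 for skeletal muscle (0.193), -0.89 for glandular stomach (0.625) and -1.72 for sex-chromosome genes (0.625). For T and NK cells camera pointed up against a median under 0.

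Between the alcohol groups, paraspeckle RNA Neat1 and the splicing factor Srrm3 were higher after 40 weeks of 15% than after 4 weeks of 20% alcohol, by 3.79 ± 0.44 and 3.51 ± 0.30 (log2 ± SE, n = 4 against 4; limma adjusted p = 8.93e-05 and 1.70e-05). The mast cell protease Cpa3 fell by 3.34 ± 0.27 (adjusted p = 1.35e-05) and the sulfotransferase Sult1d1 by 4.49 ± 0.84 (0.00150). All 4 kept direction and call after quantile normalisation. Rab38 (-5.08 ± 1.35), whose call ended when columns were scaled to 1 spread (limma adjusted p = 0.0813), and Rgs7bp (-3.55 ± 0.46), whose other kept probe had the opposite sign, were further large falls. Olfr665, an olfactory receptor gene, was not well above background on any 4-week array and was called as higher at 40 weeks (limma adjusted p = 3.22e-04). Its bound of at least 1.18-fold is for control over 4-week arrays. No bound could be set for 40 over 4 weeks. Xist (4.58 ± 1.59) and Gt(ROSA)26Sor (4.02 ± 0.85) completed the largest rises. For Gt(ROSA)26Sor the groups overlapped, the 4-week SD was 2.30, and only 2 of the 4 4-week arrays were well above background. The call of Xist ended after quantile normalisation (adjusted p = 0.126) and without 40-week replicate 3 or 4 (0.108 and 0.110) or any 1 of the 4-week replicates (4.50 to 4.65). Adh1 was lower by -1.91 ± 0.16 (1.75e-05), Aldh3a1 by -1.22 ± 0.19 (5.90e-04) and Aldh1a1 by -0.996 ± 0.19 (0.00191). Of these 3, Adh1 alone kept the call after quantile normalisation (-0.77; 0.00189), and it lost it when columns were scaled to 1 spread (-0.30), while Aldh1a1 turned to 0.32. Adh7 had -0.37 ± 0.21 (0.177) and was called at 1.22 after quantile normalisation, Aldh2 -0.18 ± 0.23 (0.550) and Cyp2e1 -1.43 ± 0.83 (0.188), and Cyp2e1 was called without 4-week replicate 3 (-2.24).

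With limma, 8621 of 20736 genes differed between the alcohol groups, 3854 higher and 4767 lower at 40 weeks, with 5512 of them among the 8336 called after quantile normalisation. Dose, length, cohort and therefore probably age differed together. Scaling of the columns to 1 spread gave 53.7% higher calls in place of 44.7%, and without 40-week replicates 3 and 4 4680 genes were called. Camera called 17 lists, 13 lower and 4 higher, and cornified envelope genes had the smallest adjusted p (median -1.37, all 48 lower, 41 fell; 2.21e-13; adjusted p = 0.324 with an estimated correlation). None of the 17 kept its call and direction after quantile normalisation, when the cornified median was -0.07, or after scaling of the columns to 1 spread, when it was 0.36. The 1 list called after quantile normalisation was cell cycle, whose median turned from 0.42 to -0.48 (camera adjusted p = 0.00170). Without 4-week replicate 2 the call of immediate early genes ended (0.14), and interferon response (0.70), B and plasma cells (1.12) and cholesterol synthesis (-0.42) were called. With an estimated correlation 0 lists were called (6 at an unadjusted p under 0.05), and fry called 22.

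In the deposited values, 1246 genes were called at 4 weeks (491 higher, 755 lower), against 145 when limma was fitted to the control and 4-week columns alone and 177 after quantile normalisation, when 52.5% were higher in place of 39.4%. The count was 722 without 4-week replicate 3, 778 without control replicate 1 and 788 without control replicate 2. Of the 1246, 859 changed in the same direction at 40 weeks (245 higher, 614 lower) and 31 in the opposite one. Independent lists would share 92.8 higher and 179 lower genes, and unchanged groups against shared controls shared at most 1 in 100 simulations. The simulated genes varied independently of each other, without shifts that run through whole arrays, so that count may set too low a level for chance. The fold changes correlated with r = 0.290 across genes, below the 0.501 of those simulations, and had a covariance of 0.108 against 0.0397, a difference of 0.0680. With the controls split 2 and 2, from 57 to 668 genes changed in the same direction and 2 to 735 in the opposite one, r ran from -0.237 to 0.379 and the covariance from -0.144 to 0.146. The split with 668 was also the one with 735, with the 4-week arrays set against control replicates 1 and 2, and 104 genes were opposite without control replicate 3. After quantile normalisation 106 genes were shared, with r = 0.0583 and a covariance of 0.0154.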

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

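The tests of dimmer Cy5 labelling, of the reference channel in lists fixed beforehand and of other organs in single arrays were chosen after their results had been seen, while those of the reference channel in the genes called as lower, of the spread of the ratios and of the 40-week scale were written before.

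Keratinocyte and smooth muscle genes were lower in the ratio at 4 weeks, and the channels behind the ratio moved apart. In the lists fixed beforehand the median Cy3 shift between slides was 1.36 for cornified envelope and 0.49 for smooth muscle genes, shares of 1.10 and 0.611 of their falls (at least 1.01 and 0.558 with each array left out), and the reference RNA should not differ between slides. A difference between slides in the reference channel may therefore account for a large part of the fall. The genes called as lower, which were chosen by their ratio, had a median Cy3 shift of 0.587, a share of 0.524 of their fall. Their median of -0.45 in Cy5 alone, a share of 0.401 (0.347 to 0.443 with each array left out), holds no Cy3 signal. It is a part of the fall that the Cy3 shift does not cover. Dimmer Cy5 labelling cannot be told apart from the Cy3 shift by this share, since a large Cy3 shift also leaves a small share to Cy5. Whether a narrower spread of the 4-week ratios contributes cannot be told apart from the rest, because scaling of every array to 1 spread took the smooth muscle median from -0.80 to -0.35 and left the cornified list at -0.67, a share of 0.545 of its fall that ran from 0.289 to 0.776 with single arrays left out. Carry-over of bright Cy5 signal into Cy3 was not tested apart and stays open, because the shift of raw Cy3, not normalised over arrays, rose with Cy5. At a control Cy3 log2 signal of 7 to 9 its median was -0.353 with Cy5 under 6 and 0.542 with Cy5 of 12 to 14. A response of the tissue to alcohol stays open as well, since slide and group coincide.

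Fold changes at 40 weeks ran against the control log2 ratio of a gene. The slope of 40-week on 4-week ratios was 0.731 among genes over 1 and 0.691 among genes under -1, against 1.16 and 0.973 for controls, as a narrower scale of all 40-week ratios in the deposited values would give. With genes divided by brightness into 3 equal parts, it was larger by 0.209 in the brightest (0.714) than in the dimmest (0.505), as weaker background subtraction on the 40-week arrays would give. The slope of control on 4-week ratios rose too, from 0.941 in the dimmest to 1.09 in the brightest. Part of the step is therefore not particular to the 40-week arrays. Both remain candidate explanations, and the step is weak ground for weaker background subtraction. Dose, length of drinking, cohort and probably age also differed between these groups and were not tested apart. The labels do not mention saccharin for the 40-week group, and some of its samples differed in sex-chromosome genes.

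The tests of 40 against 4 weeks found 8621 genes and 17 lists that differed, with limma and camera adjusted p as given here. With an estimated correlation camera called 0 of the lists (6 at an unadjusted p under 0.05) and fry called 22, and none of the 17 kept its call and direction after quantile normalisation or scaling to 1 spread. Lower at 40 weeks were cornified envelope (-1.37; camera adjusted p = 2.21e-13), fatty acid oxidation (-0.79; 2.76e-06), endothelium (-1.05; 2.25e-05), stress keratins (-1.02; 2.25e-05), smooth muscle (-0.79; 8.16e-05), alcohol and aldehyde metabolism (-0.89; 3.79e-04), enteric neurons and glia (-0.71; 0.00137), macrophages (-0.70; 0.00199) and eicosanoid synthesis (-0.98; 0.00212). The others were granulocytes and mast cells (-1.46; 0.00609), basal keratinocytes (-0.72; 0.00928), red blood cells (-0.58; 0.0116) and cytochrome P450s (-0.71; 0.0230). Higher were cell cycle (0.42; 6.26e-05), DNA repair (0.29; 0.00137), glycolysis (0.29; 0.00659) and immediate early genes (0.25; 0.0263). Olfr665 was called as higher at 40 weeks, but the size is not given because no 4-week array was well above background for it. Other single genes that differed were Xist (4.58), Gt(ROSA)26Sor (4.02), Neat1 (3.79), Srrm3 (3.51), Rab38 (-5.08), Sult1d1 (-4.49), Rgs7bp (-3.55), Cpa3 (-3.34), Adh1 (-1.91), Aldh1a1 (-0.996) and Aldh3a1 (-1.22).

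Of 291 groups tested, 24 are reported here in which a single sample stood far from the other 3, where chance gives about 1 in 20, or 14.55. The 24 leave out withheld items, which the 291 may include, and the lists and genes overlap. The counts are therefore no test of whether outlying samples are more frequent than chance gives. Glandular stomach genes had a mean deviation of 2.08 in 4-week replicate 2 against -1.07 to -0.66 in the other 3, and pancreas genes 0.16 there against -1.18 to -1.15. Interferon response genes had 0.92 in control replicate 4 against -0.49 to -0.29. Pancreas in the tissue of control replicate 3 may explain why 95.5% of pancreas genes were raised there, and glandular stomach in control replicate 4 and 4-week replicate 2 why at least 81.8% of glandular genes were raised in both. No biological explanation was tested, and the higher interferon response genes of the same arrays stay unexplained.

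Further list scores that stood apart were those of alcohol and aldehyde metabolism in 4-week replicate 3 (-0.27 against -0.07 to -0.03), the unfolded protein response and oxidative phosphorylation in 4-week replicate 2 (0.10 against -0.08 to -0.05, and 0.22 against -0.13 to -0.08) and endothelium in 4-week replicate 4 (-0.18 against -0.07 to -0.06). Adipocyte genes stood low in control replicate 1 (-0.70 against 0.64 to 0.83) and in 4-week replicate 3 (-1.58 against -0.14 to 0.10), and ribosomal protein genes high in 40-week replicate 1 (0.0527 against -0.12 to -0.09). Among log2 ratios of single genes, Cyp2e1 was low in control replicate 1 (0.82 against 5.32 to 5.98) and in 4-week replicate 3 (0.34 against 4.27 to 4.65), and Adh1 in 4-week replicate 2 (4.26 against 4.71 to 4.75). Cyp2e1 and adipocyte genes were thus low in the same arrays, and the cause was not tested. Control replicate 3 differed in Hebp1 (-1.35 against -1.70 to -1.67), Crct1 (7.94 against 7.59 to 7.63), Cpt1b (-0.79 against -0.50) and Myh11 (6.61 against 6.30 to 6.34), and control replicate 1 in Arsk (-1.46 against -1.05 to -0.99) and Gclm (-0.15 against 0.25 to 0.30). Arsk also differed in 4-week replicate 4 (-0.38 against 0.03 to 0.08) and Mocs1 in 4-week replicate 3 (2.14 against 1.80 to 1.85). At 40 weeks, Sult1d1 differed in replicate 1 (2.71 against 0.85 to 1.09), Tpx2 in replicate 2 (-2.49 against -2.17 to -2.12) and Syt1 in replicate 4 (3.25 against 2.95 to 2.98).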

How the results depend on the processing

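Scaling of the columns to 1 spread, zeros taken as missing, omission of several arrays at once, and use of scaling, Cy5 alone or (between the alcohol groups) quantile normalisation for lists were chosen after the data had been seen. Spots well above background in Cy5 made up 64.8% to 73.7% on the 4-week arrays and 73.9% to 78.8% on controls, and genes below it in a whole group have only a bound. For most of the changes below the cause was not tested.

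At 4 weeks the count of 229 genes became 558 without background correction, 136 with a smaller offset, 669 with processed signals, 75 in Cy5 alone, 475 with array weights and 145 from the deposited values. With limma it became 0 with median centring, 0 with scaling to 1 spread, and 0 without the 3 arrays with transcripts of other organs, where fewer samples remain (2819, 3165 and 4573 genes at an unadjusted p under 0.05). Without single replicates it ran from 0 to 52. The 12 lists became 0 with an estimated correlation, 6 with fry, and 10 to 16 without single replicates. Signs are given as turned only for values called in either setting. In Cy5 alone the sign turned for Asprv1 (0.0932), Gpx2 (0.15), Aldh3b2 (0.50), Cyp2f2 (0.48), Klk5 (0.14), Krt4 (0.73), Krt5 (0.33), C1qc (0.11), Pla2g4e (0.34), Car2 (0.0891) and the cornified list (0.15), because the ratio also carries the shift in Cy3. The cell cycle list turned to -0.12 after scaling, and the interferon list to -0.42 without 4-week replicate 2 (0.42, with a call, without 4-week replicate 3). Over all settings 588 values of named genes stayed on their side of the threshold, 577 lost the call and 10 turned, and of lists 582 stayed, 18 lost and 21 gained a call, and 3 turned. Among those that stayed are values uncalled in both settings, some of which changed sign, such as Adh1 and Adh7 in Cy5 alone.

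At 40 weeks the 8823 genes ran from 7213 to 9257 without single replicates and became 5058 without 40-week replicates 3 and 4, where fewer samples remain. The 20 lists became 9 after quantile normalisation, 10 after scaling and 0 with an estimated correlation, and 20 to 21 without single replicates. After quantile normalisation, again among values called in either setting, the sign turned for Cyp4b1 (0.17), Stfa1 (0.0055), Adh7 (1.61), Aldh1a1 (0.88) and the lists NRF2 targets (0.34), cytochrome P450s (0.11), basal keratinocytes (0.0374), cell cycle (-0.48), DNA repair (-0.0067), glycolysis (-0.29), adipocytes (0.12), enteric neurons (0.27) and endothelium (0.21). After scaling it turned for Stfa1 (0.72), Tpx2 (-0.0025), Adh7 (1.53), Aldh1a1 (0.87), NRF2 targets (0.38), cytochrome P450s (0.15), basal keratinocytes (0.14), cell cycle (-0.58), the unfolded protein response (-0.22), glycolysis (-0.29), adipocytes (0.17), enteric neurons (0.31) and endothelium (0.15), and camera's direction turned for DNA repair at a median of 0.0610. Of the other values, 1293 of named genes and 581 of lists stayed on their side of the threshold, uncalled ones of either sign included, 40 and 14 lost the call, and 3 and 10 gained one.

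From the deposited values the 1246 genes at 4 weeks became 177 after quantile normalisation, 799 with no filter, 145 with these groups alone, 530 after scaling and 2492 without the arrays with transcripts of other organs, and 722 to 1397 without single replicates. Between the alcohol groups the 8621 genes ran from 7093 to 8232 without single replicates and became 4680 without 40-week replicates 3 and 4. The 17 lists became 1 after quantile normalisation, 3 after scaling, 0 with an estimated correlation and 19 without 4-week replicate 2. Among values called in either setting, after quantile normalisation Adh7 (1.22), Aldh1a1 (0.32) and the lists cytochrome P450s (0.0926), cell cycle (-0.48), DNA repair (-0.18), glycolysis (-0.33), smooth muscle (0.20) and enteric neurons (0.0801) turned, and camera's direction against other genes turned for basal keratinocytes (-0.0169), stress keratins (-0.0264) and endothelium (-0.0061). After scaling Adh7 (1.66), Aldh1a1 (0.70), NRF2 targets (0.47), cytochrome P450s (0.31), cornified envelope (0.36), basal keratinocytes (0.31), stress keratins (0.10), cell cycle (-0.57), DNA repair (-0.18), immediate early genes (-0.0527), glycolysis (-0.25), smooth muscle (0.65), enteric neurons (0.37) and endothelium (0.46) turned. The 859 genes shared by both responses became 549, 201, 402, 57 and 334 in 5 splits of the controls and 668 in the other, where 735 went in opposite directions (r = -0.237), and 587 to 954 without single replicates.

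Replicate numbers did not pair the samples: deviations of same-numbered 4-week and control arrays correlated at 0.32, -0.48, 0.14 and -0.26 across genes, and not every sample correlated best with its own number. The 40-week and control arrays correlated at 0.20, 0.0929, 0.0585 and 0.20, not all over 0.1, with 2 of 4 best with their own number, and the 40-week and 4-week arrays at 0.18, -0.20, -0.19 and -0.0104. With the replicate number as a block limma called 0 genes at 4 weeks (3798 at an unadjusted p under 0.05), 8697 at 40 weeks, 912 at 4 weeks from the deposited values and 8439 between the alcohol groups, and camera 14, 20 and 17 lists. A block for slide could not be fitted, since slide and group coincide, and was not run.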

Other observations

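The genes of the next paragraph were chosen after their values were seen, as was the test of the muscle layer; the counts of splits were planned before.

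At 40 weeks single genes of lists that camera did not call in the deposited values changed there and kept direction and call after quantile normalisation. The circadian clock and NRF2 lists were then called as higher by camera, though not with an estimated correlation. Of the circadian clock, the repressor Per2 rose by 2.12 ± 0.14 (log2 ± SE; limma adjusted p = 1.50e-06; 2.66 after quantile normalisation) and the transcription factor Tef by 1.21 ± 0.15 (adjusted p = 9.38e-05; 1.69). Genes of glutathione metabolism and of NRF2 targets went both ways, with 14 higher and 5 lower calls in the list after quantile normalisation. The glutathione peroxidase Gpx2 fell by 3.42 ± 0.24 and the glutathione transferases Gsta4 and Gstm4 by 1.47 ± 0.15 and 1.38 ± 0.22, which became -1.12, -0.59 and -0.86 after quantile normalisation. Gclc, the catalytic subunit of the first enzyme of glutathione synthesis, rose by 0.77 ± 0.21 and Tkt, a transketolase of the pentose phosphate pathway, by 0.69 ± 0.13, which became 0.91 and 0.92. Of B and plasma cell genes, the antigen receptor subunit Cd79b rose by 2.31 ± 0.42 and Mzb1, a chaperone of antibody secretion, by 1.71 ± 0.28, while the IgE receptor Fcer2a fell by 2.18 ± 0.29, which became 1.33, 0.74 and -1.54. For each of these genes the 40-week and control arrays did not overlap. Scaling of the columns to 1 spread was not run for these genes.

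Less of the muscle layer in the dissected tissue was tested as an explanation for the lower smooth muscle ratios at 4 weeks. Enteric neuron and glia genes, which lie in the same layer, had a median of -0.0051 with a lower quartile of -0.33, against -0.80 for smooth muscle genes. The smooth muscle ratio also holds a Cy3 shift of 0.49, where the dimmer enteric genes had 0.06. In Cy5 alone the medians were -0.19 for smooth muscle and 0.06 for enteric genes. These values argue against muscle loss as the cause of the whole fall. They cannot tell whether a smaller loss lies behind the Cy5 part.

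Other splits of the same samples were counted for each comparison, 35 per comparison with the real one included. For the genes changed at 4 weeks (229, highest other split 0), at 40 weeks (8823, highest other 0), at 4 weeks in the deposited values (1246, highest other 4) and between the alcohol groups (8621, highest other 0), only 1 of the 35 splits, the real one, gave as many. That is the smallest share that 35 splits can give. Other splits mix the groups, which widens the spread within them and lowers their counts. The real split thus stood out, but these counts do not exclude chance. The number of lists did not stand out: 18 splits gave at least the 12 lists of 4 weeks (highest other 21), 9 at least the 20 of 40 weeks (highest other 22) and 5 at least the 17 between the alcohol groups (highest other 25). Slide and scan day follow the real split at 4 weeks, so these counts exclude nothing about them.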
